A study of Sus scrofa with 16 samples.

How the data were processed

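Total RNA from proximal and distal small intestine of preterm piglets was measured on Affymetrix porcine expression arrays. Per the labels' protocols, tissue was lysed in Trizol, RNA was purified on RNeasy columns with a DNase step, and biotin-labelled RNA was made with a 3′ IVT Express kit. Per the submitters' processing notes, GCOS 1.2, GCRMA and limma were used, and their order, settings and further versions are not given in the sources used here. The values the authors deposited are GCRMA values on a log2 scale, 1 per probe set and array, not centred per gene, with a floor at 2.14. Of all values 39.7% lay under 2.5, so the fitted size of a difference that reaches down to the floor is not well determined. Array scan dates, litters and lesion scores per array are not given in the sources used here.

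The samples were grouped by the tissue and treatment in their labels: antibiotics proximal, control proximal, antibiotics distal and control distal, 4 arrays each. Each mean is given with its SD and each difference with its SE where space allows. The pairing of segments comes from the number in the sample names, read as the animal's. It was checked by correlating, across probe sets, the residuals of the proximal and distal arrays of each of the 7 animals with both: the correlation was 0.0293 to 0.526, above 0.1 for 5 animals, and highest with the animal's own other segment for 4.

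Of 24123 probe sets 124 control probe sets were left out. Of the others 10069 were annotated with 1 gene, 198 with several and 13732 with none. Probe sets above a log2 value of 5 on at least 4 of the 16 arrays were tested, 11538 in all, of which 5759 had 1 gene, 125 several and 5654 none, for 4684 genes. A gene's value is that of its probe set with the highest mean over all arrays among those annotated with that gene alone.

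Group means were fitted over all 16 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. The comparisons were antibiotics against control in each segment, the difference of these effects (distal minus proximal), and distal against proximal. Antibiotics against control was also fitted on 1 mean per animal over 3 antibiotics and 4 control animals. P values were adjusted by Benjamini-Hochberg over all tested probe sets, with a threshold of 0.05. An "at least" fold is given where all arrays of the lower group lay at or below the filter level, and is the fold of the higher mean over that level. On animal means this asks for all arrays of the lower group's animals.

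Of 29 gene lists fixed before the data were examined 26 had at least 3 measured genes and were tested with limma's camera at a preset correlation of 0.01, with 378 of 838 list genes measured. Lists not tested for lack of members were T and NK cells (2 measured, GZMH and KLRK1), B and plasma cells (1, JCHAIN) and erythroid cells (2). P values were adjusted over the lists within a comparison. Counts of members are given over all probe sets and adjusted over the list alone. Camera with a correlation estimated per list and the rotation test fry were run as alternatives. A list of lysosomal genes was written later, after a result was seen.

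Genes were drawn by a rule fixed before the data were examined: the 10 with the largest and the 10 with the most negative change among those past the threshold, the 4 members with the largest moderated t of each called list, and 21 genes chosen in advance, of which 10 were measured. Of the list members drawn, the text names only some. IL1B, IL6, S100A8 and CD14 were filtered as dim, and LCN2, PLA2G2A, MUC2, LCT, SI, SLC10A2 and CUBN had no probe set annotated here. For the test of the difference between segments all named genes past the threshold are given.

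Alternatives were no filter and a filter at log2 7, quantile normalization again, equal array medians, trend and robust eBayes, array quality weights, an adjusted p of 0.10, the mean of all probe sets of a gene, only the arrays of 1 segment, only animals with both segments, the animal as a random block (duplicateCorrelation with statmod 1.5.0, correlation 0.172) or a fixed effect, 1 difference per animal, and each array left out in turn. The 5′ minus 3′ difference of GAPDH and actin control probe sets as a covariate, and leaving out the 2 arrays with its lowest values, were added after seeing the data. So was a fit with the position of each array on the proximal to distal axis as a covariate. On simulated data with the measured spread, log2 changes of 1, 2, 3 and 5 in 50 probe sets each were tested. Recovered were 18%, 92%, 92% and 100% in proximal and 22%, 76%, 98% and 98% in distal tissue. Of 164 and 160 calls 13 each were false. Of 130 unchanged lists 0 were called, but none with correlated genes was tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.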

Results

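Gene expression was measured in small intestinal tissue of preterm piglets that had received broad-spectrum antibiotics (ampicillin, gentamicin and metronidazole, by mouth and by injection) or saline from birth until tissue was taken on day 5. They had been born by caesarean section on gestation day 105, an age at which formula-fed piglets are prone to necrotizing enterocolitis. Tissue from a proximal and a distal segment was hybridised to an Affymetrix porcine expression array, on which each probe set reports a transcript from probes near its 3′ end. There were 16 arrays in 4 groups of 4. By the number in the sample names, read as the animal's, there were 9 animals, 7 of them with both segments. On each array between 45.1% and 46.5% of the probe sets lay above a log2 value of 5, and 11538 probe sets passed the filter and were tested. Arrays of one group correlated with each other at r = 0.963 to 0.994 across these probe sets. The number of arrays limits the precision of every comparison. RNA integrity, read as the 5′ minus 3′ difference of the GAPDH and actin control probe sets, was -3.03 ± 0.51 with antibiotics and -3.34 ± 0.81 in controls in proximal tissue (log2, SD, n = 4 each, two-sided exact permutation p = 0.571), and -3.92 ± 0.71 and -3.57 ± 0.31 in distal tissue (two-sided exact permutation p = 0.4).

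Several genes of innate defence fell in the distal small intestine of treated piglets. S100A9, a subunit of the neutrophil protein calprotectin, fell from 9.46 ± 2.22 in controls to 2.32 ± 0.05 with antibiotics (log2, SD, n = 4 each), which is at least 22.1-fold (limma adjusted p = 0.00161). DMBT1, a secreted mucosal protein that binds bacteria, fell by 4.20 on the log2 scale (SE 0.36, adjusted p = 2.3e-05). SFTPD, a collectin that opsonises microbes, fell by 4.75 (SE 0.65, adjusted p = 0.000931). PI3 (elafin) and SPAI-2, both secreted protease inhibitors of the trappin family, fell (-6.37 and -5.64, adjusted p = 0.000351 and 0.00189). TDH, which encodes the mitochondrial enzyme L-threonine dehydrogenase, rose from 2.32 ± 0.36 to 10.17 ± 0.41, at least 35.9-fold (adjusted p = 2.81e-12).

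In total 245 distal probe sets passed an adjusted p of 0.05 in limma, 118 higher and 127 lower with antibiotics, and 1823 had an unadjusted p under 0.05 where 576.9 would be expected by chance. The number of calls was 138 with no filter on dim probe sets, 143 with the mean of all probe sets of a gene, 159 with only animals with both segments, 430 when the model held only the 8 distal arrays and 1665 with array quality weights. It was between 106 (without control distal array 92) and 353 (without control distal array 88) when 1 array was left out, and it was 124, 117, 126, 120 and 150 without antibiotics arrays 85, 86 and 95, control array 83 and antibiotics array 87. Of the distal genes named here, MMP1 and C1QC passed in 0 of these 8 fits with 1 distal array left out, NEU1, UBD, TIMP1, CXCL8, ISG20 and NCF1 in 1, LCP1 in 2, C4A, TNFRSF1B and CDK5 in 3, TLR4 and KIAA0930 in 5 and CD53 and VAV1 in 7. With the 5′ minus 3′ difference as a covariate the adjusted p was 0.0662 for NEU1, 0.0608 for TIMP1, 0.0646 for MMP1 and 0.0577 for ISG20. Without the 2 arrays where that difference was lowest, a setting chosen after seeing the data, it was 0.0878, 0.123, 0.0993 and 0.122 for these 4. There it was 0.0986 for C4A, 0.0783 for TNFRSF1B, 0.0786 for CXCL8, 0.0561 for VAV1, 0.0619 for LCP1, 0.0733 for C1QC, 0.0864 for NCF1 and 0.0524 for UBD.

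The complement list was lower in distal tissue. Of its 19 measured members 18 had lower means with antibiotics, and 10 fell when adjusted over all probe sets (15 lower and 1 higher when adjusted over the list alone). The median change was -1.52 (log2, camera adjusted p = 1.2e-12; adjusted p = 0.0197 with an estimated correlation). C5, the precursor of the chemoattractant C5a, fell by 4.20 (SE 0.67, adjusted p = 0.00344). CFB, the protease of the alternative pathway, fell by 2.71 (SE 0.44, adjusted p = 0.00369), and C3, the central component, fell by 2.41 (SE 0.43, adjusted p = 0.00664). C4A, of the classical pathway, fell by 3.49 (SE 0.78, adjusted p = 0.0288).

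The antimicrobial and epithelial defence list fell too, with a median of -2.59 over 10 genes (adjusted p = 1.47e-06; adjusted p = 0.00755 with an estimated correlation). DMBT1 and S100A9 were its 2 members past the threshold over all probe sets, and 7 passed when adjusted over the list alone. DUOX2, an epithelial oxidase that makes hydrogen peroxide, had a lower mean that did not pass (adjusted p = 0.168), with all 4 treated arrays below the filter level. The neutrophil list fell with a median of -2.05 over 6 genes, all with lower means (adjusted p = 6.97e-06; adjusted p = 0.00755 with an estimated correlation). S100A9 and NCF1, a subunit of the phagocyte NADPH oxidase that fell at least 1.41-fold (adjusted p = 0.033), passed over all probe sets, and 5 passed when adjusted over the list alone. S100A9 belongs to both lists.

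**Figure D1:**
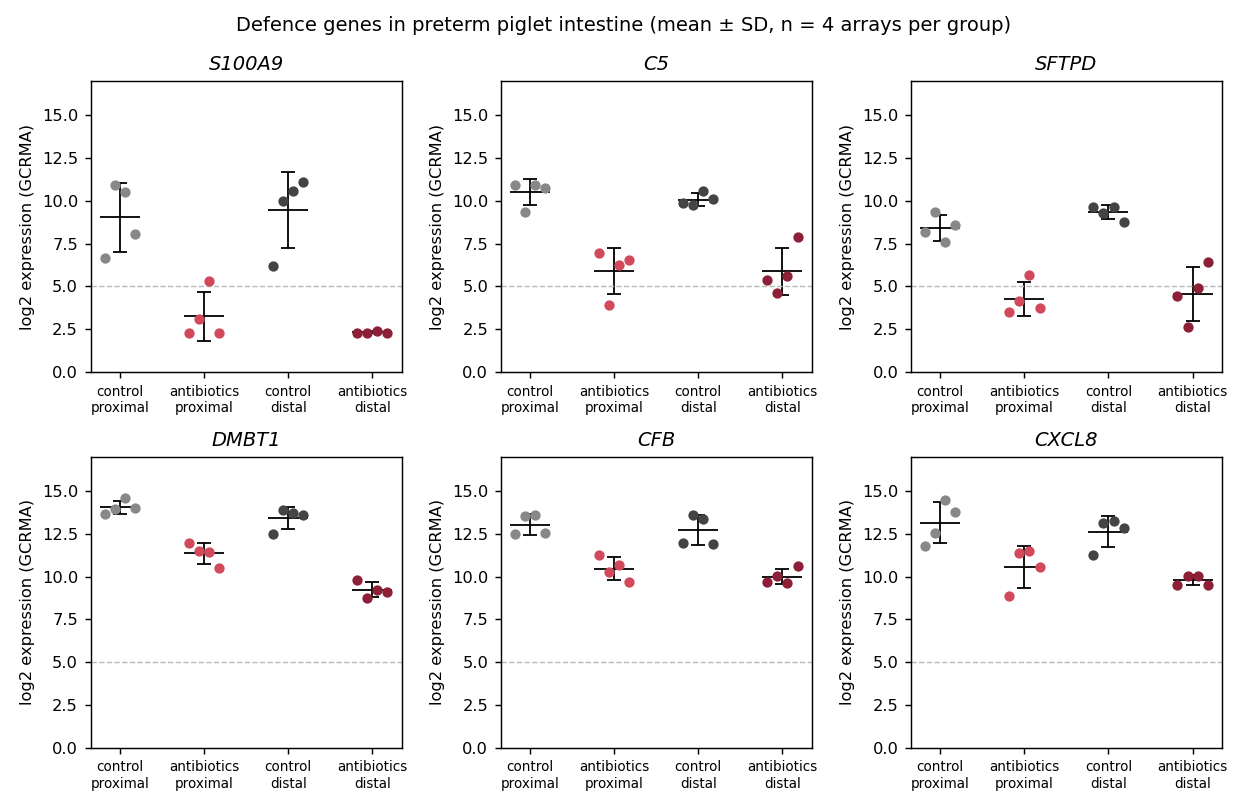
Log2 expression of 6 defence genes on each array (points), with the group mean and SD (bars, n = 4); the dashed line marks the filter level of 5. S100A9 lay at 2.32 ± 0.05 in antibiotics distal tissue and at 9.46 ± 2.22 in control distal tissue.

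Markers and products of other leukocytes were lower in distal tissue as well. The macrophage and monocyte list fell, with a median of -1.51 over 11 genes of which 9 had lower means (adjusted p = 0.000107; adjusted p = 0.108 with an estimated correlation). CD163, the haemoglobin scavenger receptor of macrophages, fell at least 16.4-fold at its brighter probe set (adjusted p = 0.0056), while the other of its 2 probe sets did not pass. C1QC, a macrophage product that starts the classical complement pathway, fell by 2.05 (adjusted p = 0.0399). Over all probe sets these 2 list members passed, against 8 lower and 1 higher when adjusted over the list alone. All 12 genes for leukocyte adhesion and recruitment had lower means (median -1.44, adjusted p = 1.85e-06; adjusted p = 0.0812 with an estimated correlation). CD53, a leukocyte tetraspanin, fell by 2.32 at 1 of its 3 probe sets (adjusted p = 0.0127), VAV1, an exchange factor of blood cells, fell by 1.65 (adjusted p = 0.014), and LCP1, a leukocyte actin-bundling protein, fell by 2.15 (adjusted p = 0.0297). These were the 3 of that list that passed over all probe sets, and 6 passed when adjusted over the list alone.

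Among sensing genes TLR2, the receptor for bacterial lipoproteins, fell by 4.01 (SE 0.45, adjusted p = 0.000166), and TLR4, the receptor for lipopolysaccharide, fell at least 1.31-fold (adjusted p = 0.0174). They were the 2 of 9 pattern recognition and NF-kB genes past the threshold (3 lower and 2 higher when adjusted over the list alone), and that list fell with a median of -0.66 (adjusted p = 0.0122; adjusted p = 0.108 with an estimated correlation). CXCL8, the neutrophil chemoattractant interleukin-8, fell by 2.85 (SE 0.63, adjusted p = 0.027) and was the only 1 of 14 cytokines and chemokines past the threshold (3 when adjusted over the list alone). The median of that list was -1.15 (adjusted p = 0.000255; adjusted p = 0.114 with an estimated correlation). TNF had a difference of -0.31 that did not pass (adjusted p = 0.468).

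Single interferon-stimulated genes fell in distal tissue. GBP1 and GBP2, interferon-induced GTPases that act on intracellular pathogens, fell (-5.13 and -5.26, adjusted p = 4.12e-05 and 0.00344). UBD, a ubiquitin-like modifier induced by interferon-gamma and TNF, fell by 5.76 (SE 1.23, adjusted p = 0.0238). IRF1, a transcription factor of the interferon response, fell by 2.06 (adjusted p = 0.0101), and ISG20, an exonuclease, fell by 2.23 (adjusted p = 0.0428). GBP1, GBP2, IRF1 and ISG20 were the 4 of 21 interferon-stimulated genes that passed, against 5 when adjusted over the list alone. The list as a whole was lower by the preset correlation (median -1.15, adjusted p = 4.44e-05; adjusted p = 0.35 with an estimated correlation), and its mean went from -1.30 to -0.74 without control distal array 92 (adjusted p = 0.0142). Of 20 antigen presentation genes 19 had lower means (median -0.97, adjusted p = 5.83e-08; adjusted p = 0.053 with an estimated correlation). TAP1, which carries peptides into the endoplasmic reticulum, fell by 2.71 (adjusted p = 0.00981), and PSMB8, a subunit of the immunoproteasome, fell at least 1.27-fold (adjusted p = 0.000896). They were the 2 that passed over all probe sets, and 9 passed when adjusted over the list alone.

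A further 9 lists were lower with antibiotics in distal tissue, and none of these calls held with an estimated correlation. The extracellular matrix list had a median of -0.58 over 20 genes (adjusted p = 0.0037; adjusted p = 0.356 with an estimated correlation), while TIMP1, an inhibitor of metalloproteinases, fell by 3.13 (adjusted p = 0.0438) and MMP1, a collagenase, fell by 1.84 (adjusted p = 0.0465; 0.052 with the animal as a random block). Both also passed when adjusted over the list alone. The apoptosis list had a median of -0.49 over 16 genes (adjusted p = 0.00164; adjusted p = 0.193 with an estimated correlation), and TNFRSF1B, a receptor for TNF, fell by 2.55 (adjusted p = 0.0247) as its only member past the threshold, also when adjusted over the list alone. Endoplasmic reticulum stress and heat shock (median -0.67, adjusted p = 0.000145; adjusted p = 0.35 with an estimated correlation) and proliferation (median -0.44, adjusted p = 0.000117; adjusted p = 0.193 with an estimated correlation) fell with 0 single members past the threshold over all probe sets, and with XBP1 of the former, a transcription factor of the unfolded protein response (-0.96), when adjusted over the list alone. Cholesterol synthesis had a median of -0.73 (adjusted p = 0.0016; adjusted p = 0.313 with an estimated correlation), with INSIG1 and SC5D at -0.95 and -1.11 past the threshold when adjusted over the list alone, and goblet cell and mucus genes a median of -0.50 (adjusted p = 0.0247; adjusted p = 0.193 with an estimated correlation). Xenobiotic and bile acid metabolism had a median of -0.35 (adjusted p = 0.0183; adjusted p = 0.176 with an estimated correlation), and FMO1, a drug-oxidising monooxygenase, fell at least 1.66-fold (adjusted p = 0.00645). Endothelial markers (median -0.69) and enterocyte digestion and absorption (median -0.37) both had an adjusted p of 0.0365, and adjusted p = 0.289 and adjusted p = 0.539 with an estimated correlation. With the animal as a random block their adjusted p was 0.0579 and 0.0568. With the 5′ minus 3′ difference as a covariate it was 0.0502 and 0.0629. In the goblet cell, endothelial and enterocyte lists 0 members passed, over all probe sets or when adjusted over the list alone. With 1 distal array left out, the endothelial list did not pass without antibiotics arrays 85 and 95 and control array 89 (adjusted p = 0.0639, 0.0858 and 0.142). Without the last its mean went from -0.65 to -0.43. The enterocyte list did not pass without antibiotics array 86 and control arrays 83, 88 and 92 (adjusted p = 0.0816, 0.106, 0.059 and 0.076). The same held for goblet cell genes without antibiotics array 95 and control array 88 (adjusted p = 0.0531 and 0.0855), xenobiotic metabolism without control array 88 (0.0885) and extracellular matrix without antibiotics array 95 (0.0844).

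In the main fit none of the 26 lists fixed in advance rose in distal tissue. A lysosomal list written later was higher at the preset correlation only (adjusted p = 7.04e-05, and 0.365 with an estimated correlation). Besides TDH, single genes that rose were XIRP2, an actin-binding protein of muscle, at least 6.59-fold (adjusted p = 0.000187), and SLC2A8, a hexose transporter, by 3.36 (SE 0.48, adjusted p = 0.0015). UPK3A, a membrane protein of the urothelium, rose at least 4.39-fold (adjusted p = 3.1e-05), and TDRP at least 2.93-fold (adjusted p = 0.000166). GNB5, a G protein beta subunit, rose by 2.56, and CDK5, a kinase, rose by 2.38 (adjusted p = 0.00051 and 0.0238). KIAA0930 rose by 2.35 and BEX3 by 2.18 (adjusted p = 0.0176 and 0.00335). NEU1, the lysosomal sialidase, rose by 2.31 (SE 0.58, adjusted p = 0.0489).

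The control distal arrays differed in how distal they looked, which was examined only after the results were seen. Over probe sets that differed between segments but not with treatment, control distal arrays 88 and 83 lay at medians of 0.50 and 0.664 on an axis from the proximal (0) to the distal mean (1), against 0.857 and 1.01 for control arrays 92 and 89 and 0.985 to 1.16 with antibiotics. For LEAP2 they lay at 11.83 and 12.13 (4.36 to 6.18 with antibiotics). For NEU1 they lay at 7.31 and 7.63 (10.07 and 8.87 for the other 2 controls). FABP6 went the other way in them (10.17 and 11.03, against 7.32 and 6.64). With this position as a covariate, whose correlation with treatment was 0.765 in distal tissue, the SE grew 1.42-fold at the median, and 93 distal probe sets were called, 62 of them among the 245, but 0 proximal ones and 1 by the difference between segments. The change of NEU1 went to 0.70 (SE 0.58, adjusted p = 0.608), that of KIAA0930 to 1.55 and that of BEX3 to 1.72 (adjusted p = 0.246 and 0.103). The means of the enterocyte and xenobiotic lists went from -0.42 to -0.15 and from -0.51 to -0.24 (adjusted p = 0.5 and 0.311), and goblet cell genes did not pass (adjusted p = 0.198). UBD, SPAI-2, C5, TAP1, C4A, TIMP1, MMP1, CXCL8, ISG20, CD53, VAV1, LCP1, C1QC, NCF1 and TLR4 did not pass either (adjusted p from 0.0573 to 0.265).

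**Figure D2:**
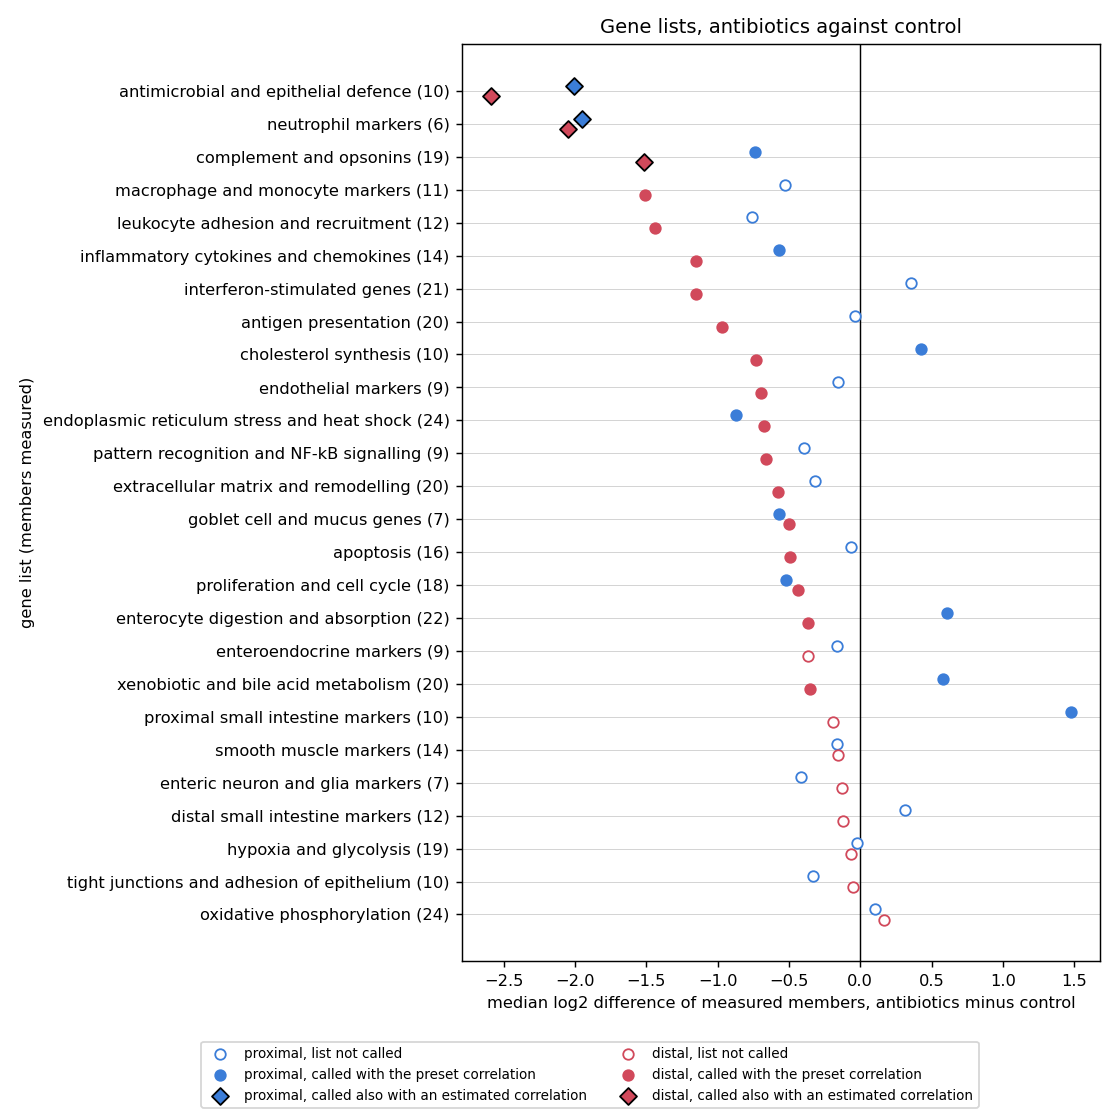
Median log2 difference between antibiotics and control arrays for each of the 26 tested lists, with the number of measured members in brackets and a point for each segment; filled points passed an adjusted p of 0.05 and diamonds also passed with an estimated correlation. The antimicrobial and epithelial defence list had the lowest medians, -2.01 in proximal and -2.59 in distal tissue.

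In the proximal intestine S100A9 and DMBT1 fell as well. S100A9 went from 9.04 ± 2.02 in controls to 3.25 ± 1.42 with antibiotics (log2, SD, n = 4 each, limma adjusted p = 0.0435). C5 fell by 4.60 (SE 0.67, adjusted p = 0.0133) and SFTPD fell by 4.16 (SE 0.65, adjusted p = 0.0187). DMBT1 fell from 14.04 ± 0.39 to 11.35 ± 0.62 and C4BPB, a chain of the complement inhibitor C4b-binding protein, fell by 2.81 (adjusted p = 0.00848 for both). ARG2, the mitochondrial arginase, fell at least 7.11-fold (adjusted p = 0.019), SAMHD1, an antiviral nucleotide hydrolase, fell by 2.70 (adjusted p = 0.0187), and CFB fell by 2.57 (adjusted p = 0.0318). APOC2, the apolipoprotein that activates lipoprotein lipase, rose from 4.84 ± 2.76 to 10.83 ± 0.83 (adjusted p = 0.0435), and SLC25A1, the mitochondrial citrate carrier, rose by 1.77 (SE 0.29, adjusted p = 0.0242). FAM114A1 rose by 2.28 (adjusted p = 0.0292) and TMEM135 rose by 1.47 (adjusted p = 0.0464).

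These were among 17 proximal probe sets past the threshold in limma, 7 higher and 10 lower, with 1483 at an unadjusted p under 0.05. The count is not firm: 3 of the 35 ways of splitting the 8 proximal arrays into groups of 4, the real one included, gave as many calls, 0 were called when the model held only these 8 arrays, 1 with no filter, 11 with the 5′ minus 3′ difference as a covariate, 30 with the mean of all probe sets of a gene, 31 with array medians set equal, 55 with only animals with both segments and 951 with array quality weights. The count was 7, 4, 5, 2 and 6 without antibiotics array 86, control array 92, antibiotics array 95, control array 83 and antibiotics array 87, and 556, 41 and 62 without control arrays 88 and 89 and antibiotics array 98. With the 5′ minus 3′ difference as a covariate the adjusted p was 0.0591 for S100A9, APOC2 and TMEM135 and 0.0553 for CFB, and without the 2 arrays where that difference was lowest it was 0.0765 for S100A9 and 0.0566 for CFB. DMBT1 and C4BPB passed in all 8 fits with 1 proximal array left out, C5 in 6, SFTPD, SAMHD1, CFB and FAM114A1 in 4, ARG2, APOC2, SLC25A1 and TMEM135 in 3 and S100A9 in 2.

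As in distal tissue, the antimicrobial and neutrophil lists were lower, and both calls held with an estimated correlation. The antimicrobial list had a median of -2.01 over 10 genes (adjusted p = 1.17e-06; adjusted p = 0.0141 with an estimated correlation), with S100A9 and DMBT1 past the threshold over all probe sets and 8 when adjusted over the list alone. The neutrophil list had a median of -1.95 over 6 genes (adjusted p = 0.000263; adjusted p = 0.0254 with an estimated correlation), with S100A9 past the threshold and 3 when adjusted over the list alone. Of 19 complement genes C5 and CFB passed over all probe sets and 7 when adjusted over the list alone (median -0.74, adjusted p = 1.17e-06; adjusted p = 0.0992 with an estimated correlation). C3 had a mean change of -1.65 and C4A of -3.57, neither past the threshold (adjusted p = 0.139 and 0.0861). CXCL8 had a change of -2.57 (adjusted p = 0.11), TLR2, below the filter level on all 4 treated arrays, a lower mean that did not pass (adjusted p = 0.211), TLR4 a change of -1.03 (adjusted p = 0.355) and TNF of 0.00 (adjusted p = 0.997).

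Of the 24 endoplasmic reticulum stress and heat shock genes 23 had lower means in treated proximal tissue, with a median of -0.87 (adjusted p = 7.23e-08; adjusted p = 0.294 with an estimated correlation). MANF (-1.45) and CRELD2 (-2.02) were among the 4 that passed when adjusted over the list alone. Goblet cell and mucus genes had a median of -0.57 over 7 genes (adjusted p = 0.000422; adjusted p = 0.0924 with an estimated correlation), and 4 passed when adjusted over the list alone, among them TFF2, a trefoil peptide, lower at least 3.01-fold and SPINK4, a goblet cell product, at -0.61. Proliferation genes had a median of -0.52 (adjusted p = 0.000492; adjusted p = 0.309 with an estimated correlation), and cytokines and chemokines a median of -0.57 (adjusted p = 0.0171; adjusted p = 0.31 with an estimated correlation). Over all probe sets 0 genes of these 4 lists passed, and when adjusted over the list alone 0 of the proliferation genes did, while CXCL8 and CXCL13, a chemokine for B cells at -3.60, did among the cytokines. The mean of the cytokine list went from -1.02 to -0.78 and -0.68 without antibiotics array 86 and control array 92 and did not pass (adjusted p = 0.126 and 0.08). That of the proliferation list went from -0.54 to -0.36 without antibiotics array 87.

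Genes of the absorptive epithelium were higher as groups in treated proximal tissue, none of them past the threshold singly over all probe sets, and none of these 4 list calls held with an estimated correlation. Enterocyte digestion and absorption rose, 19 of 22 genes with higher means (median 0.61, adjusted p = 0.000263; 0.31 with an estimated correlation). When adjusted over the list alone 3 were higher and 1 lower, with MTTP, which loads lipid onto lipoproteins, at 0.94, DGAT1, a triglyceride-forming enzyme, at 1.29, ENPEP, a brush-border aminopeptidase, at 1.08 and SLC1A1, a glutamate transporter, at -1.27. Markers of the proximal small intestine rose with a median of 1.48 over 10 genes (adjusted p = 0.000545; 0.261 with an estimated correlation). When adjusted over the list alone 0 passed. Xenobiotic and bile acid metabolism rose with a median of 0.58 over 20 genes (adjusted p = 0.0017; 0.0992 with an estimated correlation). CYP3A29, a drug-metabolising cytochrome, had a change of 4.02 (adjusted p = 0.131). When adjusted over that list alone 6 were higher and 1 lower. Cholesterol synthesis rose with a median of 0.42 (adjusted p = 0.00209; 0.377 with an estimated correlation). Only INSIG1, a sterol-responsive regulator, passed when adjusted over the list alone (1.12). Without control proximal array 88 the list's mean went from 0.45 to 0.25 (adjusted p = 0.147). Without control proximal array 83 the mean of the proximal markers went from 1.32 to 0.84 (adjusted p = 0.00463) and that of the enterocyte list from 0.63 to 0.35 (adjusted p = 0.00665). The proximal controls were not alike. Over all probe sets, on a -1 (control) to 1 (antibiotics) axis, arrays 83, 92, 88 and 89 lay at -1.12, -1.38, 0.72 and 0.05. On the proximal to distal axis controls had medians of 0.12 to 0.41 and treated arrays of -0.01 to 0.18. Position was not tested for these lists.

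All 10 probe sets that fell in proximal tissue also fell in distal tissue, against 0.11 expected for independent lists of these sizes. They include CFB, ARG2, DMBT1, C5, C4BPB, SFTPD, S100A9 and SAMHD1. Of the 7 that rose in proximal tissue 0 passed as higher in distal tissue, which says little at 0.0716 expected. Of the 17 proximal calls 15 (88.2%) had the same sign in distal tissue, and of the 245 distal calls 202 (82.4%) had the same sign in proximal tissue. The arrays of the segments are separate, but 7 animals gave both, so these counts are not independent of the animals.

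The response of the segments was compared as the antibiotic effect in distal minus that in proximal tissue. GBP1 had similar means in both proximal groups (11.24 with antibiotics and 11.29 in controls) and differed between segments by -5.09 (SE 0.71, limma adjusted p = 0.00486). PI3 lay below the filter level on all proximal arrays, so its difference of -6.46 (SE 1.11, adjusted p = 0.0277) is that of distal tissue. TDH was at the data's floor on all 8 proximal arrays, so its difference of 7.84 (SE 0.31, adjusted p = 5.8e-10) is that of distal tissue and its SE rests in part on arrays without spread. The same limit holds for XIRP2 and TDRP, which lay below the filter level on all proximal and control distal arrays, and for UPK3A, which did so on all of these but control proximal array 89 (5.10). Their differences passed (adjusted p = 0.0179, 0.0456 and 0.00202), and the sizes are bounded only by the distal rises of at least 6.59-fold, 2.93-fold and 4.39-fold. INSIG1 differed by -2.07 (SE 0.38, adjusted p = 0.0363; 0.0914 when 1 difference per animal was tested; 0.167 without the 2 arrays of the lowest 5′ minus 3′ difference; called in 5 of 16 fits with 1 array left out), and TMEM135 by -2.18 (adjusted p = 0.0281).

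Further genes in this test were MFSD2A, a lysolipid transporter, at -3.91 (adjusted p = 0.0363), GPD1L at -1.95 (adjusted p = 0.0301) and 1 of the 2 probe sets of SLC1A1 at 2.30 (adjusted p = 0.0301). In all 22 probe sets passed, 12 with a positive and 10 with a negative difference, and 764 had an unadjusted p under 0.05. The count was 39 with the animal as a random block, 9 from 1 difference per animal over the 7 animals with both segments and 11 with no filter. It lay between 10 and 44 when 1 array was left out, with 10 without antibiotics proximal array 86 or 95, control proximal array 83 or antibiotics distal array 86, 11 without control distal array 92 or 83 or antibiotics distal array 95, 14 without control proximal array 92 and 44 without control proximal array 88.

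**Figure D3:**
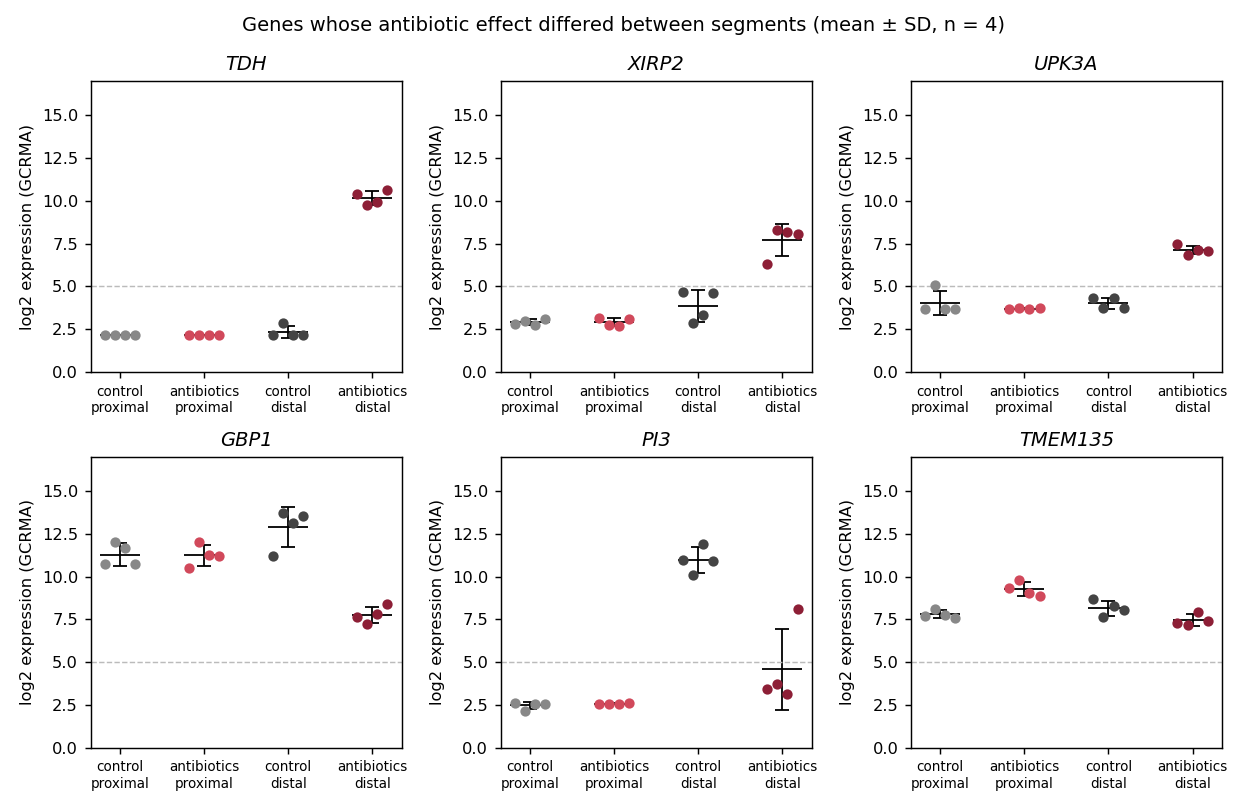
Log2 expression on each array (points), with the group mean and SD (bars, n = 4), of genes whose antibiotic effect differed between segments; the dashed line marks the filter level of 5. TDH lay at 10.17 ± 0.41 in antibiotics distal tissue and at 2.32 ± 0.36 in control distal tissue.

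By lists, 10 of 26 had a more negative effect in distal than in proximal tissue. Xenobiotic and bile acid metabolism had a median difference of -1.05 (adjusted p = 6e-07; adjusted p = 0.0259 with an estimated correlation) and was the only 1 of them that held with an estimated correlation. The cytochromes CYP2C49 (-6.39) and CYP3A29 (-5.32) did not pass over all probe sets (adjusted p = 0.407 and 0.281). They were among 7 lower when adjusted over the list alone. Cholesterol synthesis had a median of -0.96 with all 10 members negative (adjusted p = 2.26e-07, and 0.249 with an estimated correlation). INSIG1 passed over all probe sets and 2 members when adjusted over the list alone. Interferon-stimulated genes had a median of -1.37 (adjusted p = 3.33e-07; adjusted p = 0.372 with an estimated correlation), GBP1 being past the threshold and 3 when adjusted over the list alone, and the mean went from -1.59 to -1.04 without control distal array 92 (adjusted p = 0.000322). Enterocyte digestion and absorption had a median of -0.96 (adjusted p = 3.36e-07, and 0.328 with an estimated correlation). So did markers of the proximal small intestine (adjusted p = 0.00182, and 0.344 with an estimated correlation). In both 0 members passed over all probe sets. When adjusted over the list alone 3 were lower and 1 higher in the former and 2 lower in the latter. APOA4 was in both (-2.69). Xenobiotic genes and proximal markers were lower in distal tissue, so controls nearer the middle of the proximal to distal axis could give such differences. This was not tested for the lists.

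Antigen presentation had a median difference of -0.89 (adjusted p = 7.09e-06; adjusted p = 0.249 with an estimated correlation) and leukocyte adhesion of -0.66 (adjusted p = 0.00251; adjusted p = 0.344 with an estimated correlation). Apoptosis had a median of -0.53 (adjusted p = 0.00285; adjusted p = 0.344 with an estimated correlation). The complement list had a median of -0.38 and the macrophage list of -0.78 (adjusted p = 0.00802 and 0.0298; adjusted p = 0.397 with an estimated correlation for both). In these 5 lists 0 members passed, over all probe sets or when adjusted over the list alone. The mean of the leukocyte adhesion list went from -0.74 to -0.43 without control proximal array 83 and to -0.50 without control distal array 89 (adjusted p = 0.0162 and 0.0309). The complement list did not pass without antibiotics distal array 95 or control proximal array 89 (adjusted p = 0.0694 and 0.0604). Its mean went from -0.38 to -0.24 without the latter and to -0.57 without control proximal array 92. The macrophage list did not pass without antibiotics arrays 95 (distal) and 98 (proximal), control distal arrays 89 and 92 or control proximal arrays 83 and 88 (adjusted p = 0.0658, 0.144, 0.111, 0.0655, 0.161 and 0.0565). Without array 83 its mean went from -0.55 to -0.31. Apoptosis did not pass without the 2 arrays of the lowest 5′ minus 3′ difference (adjusted p = 0.0548). The neutrophil and antimicrobial lists did not pass this test (adjusted p = 0.213 and 0.375). The endoplasmic reticulum stress list had a median of 0.34 and did not pass (adjusted p = 0.269), but passed when 1 difference per animal was tested (adjusted p = 0.0158) and without control proximal array 88 (adjusted p = 0.00149). Without the 2 arrays of the lowest 5′ minus 3′ difference extracellular matrix, enteroendocrine and endothelial lists passed as more negative in distal tissue (adjusted p = 0.00422, 0.00422 and 0.046), and extracellular matrix did so with that difference as a covariate (0.039). With 1 array left out extracellular matrix passed in 4 of 16 fits, without control proximal array 89, control distal array 83 or either array of antibiotics animal 87 (adjusted p = 0.0324, 0.038, 0.0217 proximal and 0.0298 distal). Enteroendocrine genes passed without control proximal array 89 or antibiotics proximal array 87 (adjusted p = 0.003 and 0.0348), and cytokines without antibiotics proximal array 86 (0.0423).

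The segments themselves were compared to describe the tissue and to check the segment labels. FABP6, the bile acid binding protein of the ileum, was 9.32 ± 1.72 in distal tissue (log2, SD, n = 8) and higher there than in proximal tissue by 6.22 (SE 0.76, limma adjusted p = 0.000146). GCG, the precursor of the glucagon-like peptides of L cells, was 11.17 ± 0.69 in distal and 6.82 ± 1.55 in proximal tissue (SD, n = 8 each, adjusted p = 0.000105). SLPI, a secreted protease inhibitor, was higher in distal tissue by 6.63 (SE 0.31, adjusted p = 1.26e-09) and SLC26A3, the chloride and bicarbonate exchanger of ileum and colon, by 5.29 (SE 0.77, adjusted p = 0.000698). GATA4, a transcription factor that marks the proximal small intestine, was 5.52 ± 0.95 in proximal and 2.44 ± 0.18 in distal tissue (adjusted p = 4.4e-05), at least 1.43-fold. TMPRSS15, the duodenal enzyme enteropeptidase that activates trypsinogen, was lower in distal tissue by -6.71 (SE 0.72, adjusted p = 4.29e-05), and SLC2A5, the fructose transporter, by -3.56 (SE 0.54, adjusted p = 0.000943).

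Other genes that differed between segments were the lipid carriers APOE and APOC2, higher in distal tissue by 3.74 and 5.90 (adjusted p = 0.000246 and 0.000221), and DPEP1, a brush-border dipeptidase, higher at least 4.35-fold (adjusted p = 2.79e-06). EPHX1, an epoxide hydrolase, and MLN, the hormone motilin, were higher in proximal tissue at least 4.59-fold and 4.36-fold (adjusted p = 2.92e-08 and 0.000868). TM4SF5 was lower in distal tissue by -4.47 (adjusted p = 4.9e-05). The protease inhibitors SPAI-2 and PI3 were higher in distal tissue at least 15.4-fold and 6.86-fold (adjusted p = 4.12e-06 and 3.73e-05). Both fell there with antibiotics (-5.64 and -6.37). AMBP, the precursor of bikunin, was higher in proximal tissue at least 5.21-fold (adjusted p = 0.00546). CDA, cytidine deaminase, differed by -3.20 (adjusted p = 0.0281; 0.101 with the 5′ minus 3′ difference as a covariate; called in 7 of 16 fits with 1 array left out) and APOM, an apolipoprotein, by -4.35 (adjusted p = 0.0406). LEAP2 and CYP2C49 differed by -4.66 and -4.38 (adjusted p = 0.00594 and 0.0164; 0.0714 and 0.113 with the animal as a fixed effect). TDH was higher in distal tissue at least 2.37-fold (adjusted p = 7.34e-11; 0.175 with the animal as a fixed effect), since it was above the filter level only on the antibiotics distal arrays.

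In all 637 probe sets differed between segments, 396 higher and 241 lower in distal tissue. The count was 286 with the animal as a fixed effect over the 7 animals with both segments, 404 with no filter, and between 452 and 648 when 1 array was left out. With that fixed effect FCN2, ENPEP, MEP1B, C9, C1QC, SLC2A1, CCL25, NDUFV1, AURKA and APOM were no longer past the threshold (adjusted p = 0.0529, 0.0605, 0.0663, 0.139, 0.158, 0.0871, 0.0782, 0.078, 0.0661 and 0.201). With the 5′ minus 3′ difference as a covariate C1QC, MEP1B, SLC2A1, NDUFV1, AURKA, APOM and CYP2C49 did not pass (adjusted p = 0.0794, 0.0608, 0.06, 0.06, 0.15, 0.0836 and 0.0683).

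**Figure D4:**
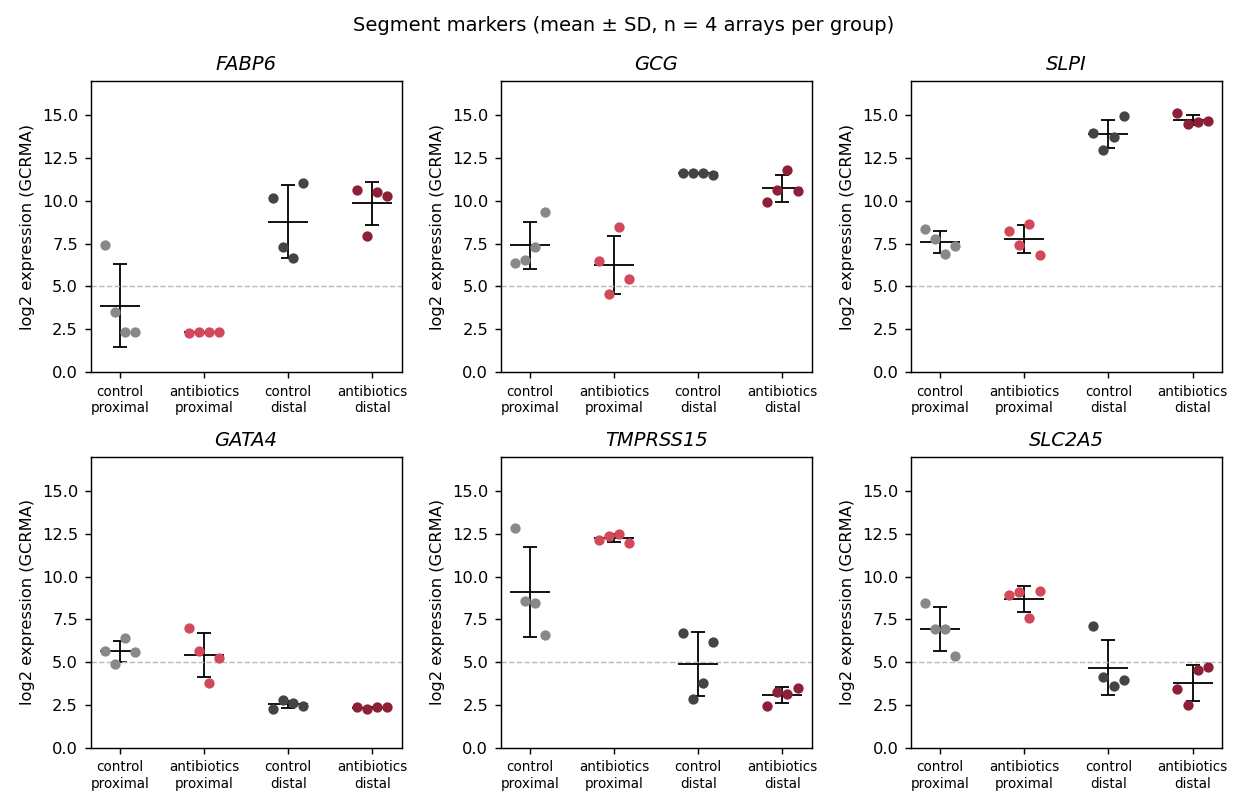
Log2 expression on each array (points), with the group mean and SD (bars, n = 4), of 3 genes higher in distal and 3 genes higher in proximal tissue; the dashed line marks the filter level of 5. SLPI was 14.31 ± 0.72 over the 8 distal and 7.69 ± 0.69 over the 8 proximal arrays.

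Markers of the proximal small intestine were lower in distal tissue as a list, with 5 of 10 past the threshold over all probe sets and 8 when adjusted over the list alone (median -1.54, adjusted p = 1e-09; adjusted p = 0.0433 with an estimated correlation). Xenobiotic and bile acid metabolism was lower too, with 8 lower and 1 higher of 20 (11 lower and 1 higher when adjusted over the list alone; median -0.92, adjusted p = 4.86e-08; adjusted p = 0.0119 with an estimated correlation). Among its members CYP27A1, a bile acid synthesis enzyme, was higher in proximal tissue at least 1.99-fold (adjusted p = 0.00436), and GSTO1, a glutathione transferase, was lower in distal tissue by -1.60 (adjusted p = 0.000808). Markers of the distal small intestine were higher in distal tissue, with 4 higher and 1 lower of 12 (8 higher and 1 lower when adjusted over the list alone; median 1.03, adjusted p = 0.00126; adjusted p = 0.222 with an estimated correlation).

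A further 5 lists were lower in distal tissue and lost the call with an estimated correlation. Complement had a median of -0.39, with FCN2, a lectin that starts complement activation, lower by -1.39 (list adjusted p = 0.00109; adjusted p = 0.481 with an estimated correlation). Proliferation had a median of -0.28 (adjusted p = 0.00809; adjusted p = 0.569 with an estimated correlation; 0.0632 with the animal as a fixed effect), and AURKA, a mitotic kinase, was lower by -1.06 at 1 of its 2 probe sets. Leukocyte adhesion had a median of -0.33 (adjusted p = 0.0309; adjusted p = 0.569 with an estimated correlation), with CCL25, a chemokine of the small intestine that attracts gut-homing lymphocytes, lower by -1.64. Oxidative phosphorylation, and hypoxia and glycolysis, had medians of -0.15 and -0.17 (adjusted p = 0.0197 and 0.0403; 0.69 and 0.607 with an estimated correlation). With the animal as a fixed effect the adjusted p of these last 3 lists was 0.0607 each. With the 5′ minus 3′ difference as a covariate their means went from -0.32 to -0.12, from -0.17 to -0.08 and from -0.18 to -0.12 (adjusted p = 0.163, 0.298 and 0.177). With 1 array left out leukocyte adhesion passed in 11 of 16 fits (means -0.18 without control distal array 83 and -0.48 without control proximal array 83), oxidative phosphorylation in 14 and hypoxia in 9 (-0.08 without control proximal array 92). Over all probe sets 3, 1, 1, 1 and 1 members of these 5 lists passed, and 4, 2, 2, 1 and 1 when adjusted over the list alone.

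The last comparison used each animal once, as the mean of its segments, in the 3 antibiotics and 4 control animals with both. S100A9 fell at least 19.1-fold (limma adjusted p = 0.0252), and DMBT1 fell by 3.56 (SE 0.29, adjusted p = 0.00516). SFTPD, C5 and C4BPB fell too (-4.66, -4.37 and -2.95, adjusted p = 0.00764, 0.017 and 0.00764). UBD fell by 5.11 (SE 0.57, adjusted p = 0.00908), TLR2 fell by 2.86 (adjusted p = 0.0301) and TLR4 fell at least 1.25-fold (adjusted p = 0.0468). CYP2J34, a cytochrome P450, rose by 1.79 (adjusted p = 0.0272) and SLC2A8 rose by 2.33 (adjusted p = 0.00908). TDH rose at least 2.17-fold (adjusted p = 0.000282), which averages the distal rise with proximal arrays at the floor. C4A fell by 3.87, CFB fell by 2.63 and FAM26F fell by 2.59 (adjusted p = 0.0488, 0.0468 and 0.00764). XIRP2 rose at least 1.51-fold (adjusted p = 0.0175), and TDRP and UPK3A passed as higher (adjusted p = 0.0468 and 0.0488). CXCL8 and CD163 had lower means, neither past the threshold (adjusted p = 0.0768 and 0.0572; 0.00678 and 0.0018 with the animal as a random block over all 16 arrays).

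On animal means 40 probe sets passed, 14 higher and 26 lower, with 1859 at an unadjusted p under 0.05. This count is not firm either: 2 of the 35 ways of splitting the 7 animals into 3 and 4, the real one included, gave as many, the count was 1 with no filter and 328 with the animal as a random block over 16 arrays, and it was 25, 22, 19, 21 and 25 without animals 83, 86, 87, 92 and 95 and 416 without animal 88. Without the 2 arrays of the lowest 5′ minus 3′ difference, a setting chosen after seeing the data, 12 were called. The adjusted p was then 0.191 for S100A9, 0.0587 for DMBT1, 0.0617 for C4BPB, 0.0609 for UBD, 0.164 for TLR2, 0.193 for TLR4, 0.179 for CYP2J34, 0.109 for SLC2A8, 0.224 for C4A, 0.195 for CFB, 0.0802 for FAM26F, 0.135 for XIRP2, 0.0509 for TDRP and 0.111 for UPK3A. In the 7 fits with 1 animal left out DMBT1, SFTPD, C4BPB, FAM26F and TDH passed in all, UBD and SLC2A8 in 6, C5 in 4, C4A and XIRP2 in 3, TLR2, TDRP and UPK3A in 2 and S100A9, TLR4, CFB and CYP2J34 in 1. With the 5′ minus 3′ difference as a covariate the adjusted p was 0.0612 for TLR4, 0.0703 for C4A, 0.0566 for CFB, 0.0615 for TDRP and 0.06 for UPK3A.

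On animal means 12 lists fell and 1 rose, and 0 of these 13 calls held with an estimated correlation. Complement had a median of -1.10 (adjusted p = 1.44e-09; adjusted p = 0.228 with an estimated correlation), with 3 of 19 lower over all probe sets and 13 lower and 1 higher when adjusted over the list alone. The antimicrobial list had a median of -1.81 with all 10 members negative (adjusted p = 7.77e-07; adjusted p = 0.0722 with an estimated correlation), and the neutrophil list a median of -2.08 (adjusted p = 5.67e-05; adjusted p = 0.103 with an estimated correlation). Endoplasmic reticulum stress had a median of -0.78 with all 24 members negative (adjusted p = 1.29e-06; adjusted p = 0.444 with an estimated correlation). Proliferation had a median of -0.53 with all 18 members negative (adjusted p = 1.43e-05; adjusted p = 0.229 with an estimated correlation), and 6 of them, among them RRM2 at -1.29 and PCNA at -0.73, passed when adjusted over the list alone. The lists of leukocyte adhesion (median -1.24), antigen presentation (median -0.65) and cytokines (1 of 14 with a higher mean) had adjusted p of 0.000105, 0.000106 and 0.000677, and adjusted p = 0.229 with an estimated correlation for each. Macrophage markers (median -1.07, adjusted p = 0.00104; adjusted p = 0.32 with an estimated correlation), goblet cell genes (median -0.52, adjusted p = 0.00367; adjusted p = 0.229 with an estimated correlation), extracellular matrix (median -0.54, adjusted p = 0.00819; adjusted p = 0.471 with an estimated correlation) and pattern recognition (median -0.51, adjusted p = 0.0184; adjusted p = 0.303 with an estimated correlation) fell as well. Markers of the proximal small intestine were the list that rose (median 0.71, adjusted p = 0.0484; adjusted p = 0.544 with an estimated correlation; 0.136 with the animal as a random block). That list passed in 2 of 7 fits with 1 animal left out. Its mean went from 0.64 to 0.42 without control animal 83 and to 0.98 without control animal 88, and its adjusted p was 0.0636 with the 5′ minus 3′ difference as a covariate. Extracellular matrix did not pass without control animal 89 or antibiotics animal 95 (adjusted p = 0.0962 and 0.138). Without the 2 arrays of the lowest 5′ minus 3′ difference extracellular matrix and the proximal markers did not pass (adjusted p = 0.0671 and 0.135). Lists that did not pass with all 7 animals but did with 1 left out were apoptosis, lower without animals 83, 89 and 95 (adjusted p = 0.0482, 0.018 and 0.0201), smooth muscle, lower without animals 83, 86 and 92 (0.0124, 0.0341 and 0.0107), endothelial markers, lower without animal 86 (0.035), and oxidative phosphorylation, higher without animals 83 and 87 (0.0463 and 0.0123). Interferon-stimulated genes did not pass (adjusted p = 0.0807) but did with the animal as a random block (adjusted p = 0.0245). They also passed without animals 83, 88 and 95 (adjusted p = 0.016, 0.013 and 0.0201). Their direction rests on 1 animal, since without control animal 92 the mean went from -0.52 to 0.03 (adjusted p = 0.4).

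The lists that passed in neither segment against control were smooth muscle, enteric neuron and glia, enteroendocrine, hypoxia and glycolysis, tight junctions, oxidative phosphorylation and distal small intestine markers. Their distal medians were -0.16, -0.13, -0.37, -0.07, -0.05, 0.17 and -0.12 (adjusted p = 0.159, 0.234, 0.105, 0.296, 0.466, 0.183 and 0.824), and their proximal medians -0.16, -0.42, -0.16, -0.03, -0.33, 0.10 and 0.32 (adjusted p = 0.563, 0.163, 0.958, 0.958, 0.192, 0.0661 and 0.474). In 3 of these the median, the mean and the direction of the test did not share a sign: enteroendocrine (proximal median -0.16, mean 0.14, test up), hypoxia and glycolysis (proximal median -0.03, mean -0.16, test up) and distal small intestine markers (distal median -0.12, mean 0.14, test down). Markers of the proximal small intestine had a distal median of -0.19 (adjusted p = 0.641). Oxidative phosphorylation passed as higher in proximal tissue without antibiotics arrays 86 and 87 and control array 83 (adjusted p = 0.0484, 0.0125 and 0.023). In distal tissue it did so without antibiotics array 87 and control array 83 (adjusted p = 0.0418 and 0.0487) and without the 2 arrays of the lowest 5′ minus 3′ difference (0.0481). Smooth muscle markers passed as lower in distal tissue without antibiotics array 85 and control arrays 83 and 92 (adjusted p = 0.049, 0.0362 and 0.0282). The macrophage, leukocyte adhesion, antigen presentation and interferon lists, which fell in distal tissue, had proximal medians of -0.53, -0.76, -0.04 and 0.35 (adjusted p = 0.0823, 0.0771, 0.262 and 0.262). The proximal macrophage and leukocyte adhesion lists passed with the 5′ minus 3′ difference as a covariate (adjusted p = 0.0238 and 0.0481), with means going from -0.64 to -0.77 and from -0.80 to -0.91, so these 2 are not shown to be confined to distal tissue. Both also passed without control proximal array 83 (adjusted p = 0.00592 and 0.00388), as did proximal antigen presentation and pattern recognition (adjusted p = 0.0278 and 0.0406). Leukocyte adhesion passed without antibiotics proximal array 95 too (adjusted p = 0.0259). The interferon list passed as higher without control proximal array 92 (mean from 0.29 to 0.84, adjusted p = 0.000689). The lists for pattern recognition, extracellular matrix, endothelial markers and apoptosis had proximal medians of -0.40, -0.32, -0.16 and -0.07 (adjusted p = 0.0871, 0.192, 0.563 and 0.995).

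Among genes chosen before the data were examined, FABP2, the fatty acid binding protein of enterocytes, had changes of 0.66 in proximal and -0.39 in distal tissue with antibiotics (adjusted p = 0.408 and 0.612). FABP6 had changes of -1.58 and 1.06 (adjusted p = 0.588 and 0.694), and GATA4 of -0.21 and -0.18 (adjusted p = 0.899 and 0.901), and neither passed. S100A9 had a difference of -0.25 between segments, CXCL8 of -0.64, C3 of -0.55, CFB of -0.39 and TNF of 0.19, none past the threshold (adjusted p = 0.917, 0.517, 0.382, 0.594 and 0.531). TLR2 was higher in distal tissue by 2.17 (adjusted p = 0.000714), where it fell by 4.01 with antibiotics. TLR4 did not pass (-0.47, adjusted p = 0.512).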

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

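The tests of animal 88's group label and of RNA integrity, of leukocyte loss and of the place along the intestine, and the counts of other splits, were chosen only after the result was seen; for neutrophils the demand for at least 6 markers was added after its value was known.

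Among named genes 36 of 611 group tests (Dixon's test at 95%, 4 arrays) had 1 array far from the other 3, about the 1 in 20 that chance gives. Among the 32 genes that passed in either segment it was 7 of 106. Groups with all arrays at or below a log2 value of 5 were not tested.

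In control proximal tissue array 88 lay apart for CYP3A29 (14.54, against a mean of 9.47 for the other 3), DGAT1 (11.23 against 10.18), TM4SF5 (12.80 against 8.92) and TNF (5.46 against 5.45). Array 89 lay apart for C5 (9.36), SC5D (12.15) and UPK3A (5.10), array 92 for ISG20 (8.73) and TLR2 (6.40), and array 83 for TNFSF10 (4.76). In control distal tissue array 88 lay apart for C1QA (6.69), C1QC (9.96), GNB5 (5.56), SLC2A5 (7.10) and TAP1 (8.87), array 89 for LCP1 (8.70), MSMO1 (12.59) and SLC26A3 (10.95), and array 83 for CYP2C49 (2.73).

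In antibiotics proximal tissue array 98 lay apart for CYP27A1 (4.61), CYP2J34 (12.44), SLC2A5 (7.58) and XBP1 (11.72), array 95 for ATF4 (11.50), and array 87 for TNF (5.48) and TYROBP (7.47). In antibiotics distal tissue array 87 lay apart for C1QC (5.48), GSTO1 (11.16), PI3 (8.13) and PTX3 (6.68), array 85 for C4BPB (6.05), TNF (5.61) and XIRP2 (6.33), array 86 for FABP6 (7.97), and array 95 for FOLH1B (9.82) and SLC1A1 (12.28). The 3 results for TNF rest on values that were otherwise constant, and are small.

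The antibiotic effect differed between segments, by the test of the difference itself, for INSIG1 (-2.07), PI3 (-6.46), UPK3A (3.46), TMEM135 (-2.18), GPD1L (-1.95), MFSD2A (-3.91), GBP1 (-5.09 and -6.25 at 2 probe sets), TDH (7.84), TDRP (2.22), SLC1A1 (2.30), XIRP2 (3.84) and 10 probe sets without a single gene name. The sizes for TDH, TDRP, XIRP2 and PI3 rest on proximal arrays all at or below a log2 value of 5, and that for UPK3A on 7 of 8 such arrays. It differed for the lists of antigen presentation (median -0.89), apoptosis (-0.53), cholesterol synthesis (-0.96), complement (-0.38), enterocyte genes (-0.96), interferon-stimulated genes (-1.37), leukocyte adhesion (-0.66), macrophages (-0.78), proximal markers (-0.96) and xenobiotic metabolism (-1.05).

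Other ways of splitting the arrays into groups of these sizes were counted for each comparison. In proximal tissue 3 of 35 splits, the real one included, called at least the real 17 probe sets, so chance cannot be excluded by this count. The highest other split called 1103, with control array 88 grouped with antibiotics arrays 86, 87 and 95, which points to a structure of the samples. In distal tissue 1 of 35 splits, the real one, gave as many as 245 (highest other 1), so it ranked first. As 1 of 35 is the smallest share this count can give, it does not by itself exclude chance. For the difference between segments 2 of 100 splits called at least the real 22, but these parted the arrays of an animal, and the other one called 518, which again points to a structure of the samples. With an animal's arrays kept together (animals with 1 segment always treated) 1 of 35 splits, the real one, called 22 (highest other 6). This does not exclude chance either. From 1 difference per animal 2 of 35 splits called at least the real 9, so chance cannot be excluded. Animals 83, 89 and 92 against the rest called 13. For distal against proximal tissue 1 of 100, the real one, gave 637 (highest other 190), so it ranked first among those drawn. Only 3 of the drawn splits parted all 7 pairs of segments as the real one does, and of these the highest called 1. On animal means 2 of 35 splits called at least the real 40, so chance cannot be excluded, and the highest other, animals 83, 89 and 92 against the rest, called 329, which points to a structure of the samples.

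The first pattern weighed is that control proximal array 88 lay among the antibiotics arrays, at 0.72 on an axis from -1 (control) to 1 (antibiotics), while antibiotics array 98 lay at -0.35. A difference in RNA integrity is argued against, since with its trend taken out the position was 0.82. A mislabelled sample stays open: over 126 probe sets array 88 lay at a median 0.363 of the way from the antibiotics mean (0) to the control mean (1), with quartiles of 0.0918 and 0.745, and above all 4 antibiotics arrays at 58, while antibiotics array 98 lay at a median of 0.336 there (quartiles 0.0917 and 0.565). A wrong group label of the animal is argued against: its distal array lay at a median of 0.489 over 433 probe sets (quartiles 0.267 and 0.821), while the 4 antibiotics distal arrays, each placed without itself, lay between 0.00789 and 0.121 (SD 0.048) and the other 3 control distal arrays between 0.641 and 1.01. This does not touch a wrong label of the proximal sample alone, and no biological explanation was tested, as no lesion score per array was in the labels used.

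The second pattern is the 10 probe sets lower with antibiotics in both segments (median change -2.89 in proximal and -3.14 in distal tissue). A difference in RNA integrity is argued against as the whole cause: with it as a covariate the proximal median was -2.88, and 7 of the 10 were still called there and all 10 in distal tissue. The place of the distal tissue along the intestine is argued against likewise, since with the position of each array as a covariate the distal median was -3.64 and 8 were still called there, though 0 in proximal tissue (median -3.06), where the SE grew 1.16-fold. Fewer macrophages and monocytes stay open. Their 11 markers had a distal median of -1.51 and a proximal one of -0.53 (SD 1.22), against a smallest fall there of -2.57 among the 10. But 4 are in another list, and the 10 were picked as calls. Fewer neutrophils stay open too (median -1.26, SD 1.31, only 5 markers outside the pattern). Neither can be told apart here from a lower expression under the treatment itself.

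The third pattern is the 11 probe sets higher with antibiotics in distal tissue by the test of the difference, 4 of them with a gene name (TDH, UPK3A, XIRP2 and TDRP). A difference in RNA integrity is argued against as the whole cause: with it as a covariate the median difference was 3.24, from 3.31, and 8 were still called. Of the 11, 6 lay at or below log2 5 on all arrays outside antibiotics distal tissue, so their fitted sizes are no bounds, and the median over the other 5 was 3.24, from 3.46. With each array's position as a covariate the median distal change was 3.09, from 3.12, and 10 were still called there. By the test of the difference, where the SE grew, 1 was (median 2.95). This argues only weakly against the place of the distal tissue as the whole cause. Of the 11, 9 lay at or below log2 5 on all control distal arrays. The treatment itself stays open as a hypothesis, found and tested on the same arrays.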

How the results depend on the processing

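The settings with the integrity covariate (5′ minus 3′ difference), with the position covariate and without the 2 arrays of lowest integrity were chosen only after the result was seen. Counts moved by more than 1.5 times as follows, in the order proximal (17), distal (245), difference (22), segments (637) and animal means (40): with no filter 1, 138, 11, 404 and 1; with array quality weights 951, 1665, 210, 1328 and 922; at an adjusted p of 0.10 they were 77, 478, 38, 985 and 176. With the mean of all probe sets of a gene they were 30, 143 and 286 (proximal, distal, segments), where fewer features are tested. The proximal count was 31 with array medians set equal, 0 with only the 8 arrays of the segment, 55 with only animals with both segments, 11 with the integrity covariate and 29 without the 2 arrays of lowest integrity. The distal count was 430 with only its 8 arrays and 159 with only animals with both segments. The difference count was 39 with the animal as a random block, 9 with 1 difference per animal and 12 without the 2 arrays of lowest integrity. With the position covariate the proximal, distal and difference counts were 0, 93 and 1. The segment count was 286 with the animal as a fixed effect. The animal mean count was 328 with the animal as a random block and 12 without the 2 arrays of lowest integrity. With 1 array or animal left out the counts were 2 to 556, 106 to 353, 10 to 44 and 19 to 416 for proximal, distal, difference and animal means, and 452 to 648 for segments, which stayed within 1.5 times. The lowest and highest proximal counts came without control arrays 83 and 88. The cause was not tested. Quantile normalization again, a filter at log2 7 and trend and robust fitting kept all 5 counts within 1.5 times.

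The random block also ended the call of MMP1 and brought those of TYROBP (adjusted p = 0.049), GBP2 for the difference (0.0319), CD46, RAC2 and CDC20 between segments (0.0278, 0.0321 and 0.032) and, on animal means, 19 genes, and ended the call of the hypoxia and glycolysis list between segments (0.0681). It changed no other call than these and those given with the results. Of 130 list tests 52 lost their call with an estimated correlation and 31 with the rotation test. Of 297 gene results 21 lost their call with the integrity covariate, and 34 lost and 3 gained it without the 2 arrays of lowest integrity. With 1 array left out 263 of 3044 gene results lost their call and 66 gained it, and 43 and 34 of 1430 list results did.

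Directions changed for 9 gene and 85 list results, of which 0 were called in either setting. The alternative values had sizes up to 0.33 and 0.26, and the values they replace sizes up to 0.73 (TIMP2 in distal tissue) and 0.52 (the interferon list on animal means, -0.52 with all animals). The values are log2 changes, for a list the mean over its members. With array medians set equal, that of oxidative phosphorylation (difference) was -0.046. With the mean of all probe sets of a gene, that of TIMP2 (distal) was -0.085. With the animal as a fixed effect, the segment values were S100A9 0.14, apoptosis 0.016 and enteric neuron and glia markers 0.046. Enteroendocrine markers were 0.085 and interferon-stimulated genes 0.16 there. With 1 difference per animal, the values were distal small intestine markers (difference) -0.067, proliferation and cell cycle (difference) 0.14. With the integrity covariate, the values were proximal small intestine markers (distal) 0.037 and smooth muscle markers (difference) 0.057. Between segments they were antigen presentation 0.10, apoptosis 0.11, enteric neuron and glia markers 0.032 and enterocyte digestion and absorption 0.026. Interferon-stimulated genes were 0.099 there, smooth muscle markers 0.035 and tight junctions and adhesion 0.0011. Without the 2 arrays of lowest integrity, the values were S100A9 (segments) 0.060, distal small intestine markers (difference) -0.041, enterocyte digestion and absorption (segments) 0.058, enteroendocrine markers (segments) 0.13, enteroendocrine markers (animal means) 0.26. With 1 array left out the ranges of the results that changed sign were as follows. In the proximal comparison, distal small intestine markers -0.18 to 0.40, smooth muscle markers -0.27 to 0.054, GATA4 -0.73 to 0.33, apoptosis -0.21 to 0.086, hypoxia and glycolysis -0.26 to 0.044, enteroendocrine markers -0.038 to 0.46, interferon-stimulated genes -0.15 to 0.84, TNF -0.0046 to 0.0087. For the difference, proliferation and cell cycle -0.24 to 0.084, distal small intestine markers -0.26 to 0.32, oxidative phosphorylation -0.10 to 0.096, enteric neuron and glia markers -0.15 to 0.18, inflammatory cytokines and chemokines -0.53 to 0.070, smooth muscle markers -0.25 to 0.072. Between segments, enterocyte digestion and absorption -0.18 to 0.078, S100A9 -0.65 to 0.29, enteroendocrine markers -0.21 to 0.10, apoptosis -0.15 to 0.0036, enteric neuron and glia markers -0.14 to 0.028, interferon-stimulated genes -0.36 to 0.20, macrophage and monocyte markers -0.019 to 0.21. In the distal comparison, proximal small intestine markers -0.25 to 0.067. On animal means, distal small intestine markers -0.059 to 0.25, enteroendocrine markers -0.30 to 0.061, cholesterol synthesis -0.30 to 0.063, interferon-stimulated genes -0.78 to 0.033, xenobiotic and bile acid metabolism -0.0021 to 0.39. The cause was not tested.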

Other observations

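The list of lysosomal genes was written after NEU1 was seen to rise; the test itself was fixed before its value was known, but the demand that the call also hold with an estimated correlation, and the test of the place along the intestine, were added after it was seen.

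NEU1, a lysosomal enzyme, rose in distal tissue with antibiotics, which led to the hypothesis that lysosomal genes rose as a group. Over 26 other lysosomal genes the distal median was 0.72, 22 were positive and 0 passed singly (camera adjusted p = 7.04e-05; adjusted p = 0.365 with an estimated correlation). The proximal test gave an adjusted p of 0.000838 (adjusted p = 0.365 with an estimated correlation), and the difference between segments did not pass (adjusted p = 0.319). The same genes were higher in distal than in proximal tissue, 12 of them singly (adjusted p = 1.67e-13; adjusted p = 0.103 with an estimated correlation). Since the distal call rests on the preset correlation, the hypothesis is neither upheld nor excluded. NEU1 was itself higher in distal tissue. With the position covariate its change was 0.70 (SE 0.58), from 2.31 (SE 0.58). Its rise may thus come from control distal arrays 83 and 88 looking less distal.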
